A study of Mus musculus with 8 samples.

How the data were processed

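MBL2 cells were sampled 24 h after treatment, with 2 libraries each for control, romidepsin, talazoparib and the combination. Per the labels' protocols, cells in RPMI-based medium in 96-well plates received a single dose, material of 3 wells was used, RNA was extracted with TRIzol and treated with DNase, and libraries were made with the TruSeq Stranded mRNA kit and selected for fragments of 200 to 400 bp. Groups and replicate numbers came from the sample titles. The doses are not given in the sources used here.

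Reads were aligned to the mouse genome mm10 with HISAT2 and assembled with StringTie, per the submitters' processing notes. Their versions and settings are not given in the sources used here. Per the file headers, the authors deposited 1 table with raw read counts per gene, and these are whole numbers. The table also holds FPKM values, fragments scaled to length and library size, which the authors computed. The authors' normalised values are on a log2 scale, and from the values they equal log2(count × a factor per library + 1), with a product of factor and library total of 957560 to 1050190. The authors' fold changes are linear and signed, so that a fall is minus the inverse ratio, per the file headers and the values. Unadjusted and adjusted p-values of 6 comparisons stand beside them, per the file headers, from a test of the authors whose tool is not named in the sources used here. Log2 values, fold changes and p-values of the authors entered no test here, and their adjusted p-values were only counted.

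Total counts ran from 28419156 to 38913292 per library, and the 10 most abundant genes took 4.14% to 5.75% of them. The table lists 12260 genes, each with at least 1 read in all 8 libraries, so genes silent in any library are not analysed here. Of the gene IDs, 12237 were matched to the reference annotation (GENCODE, GRCm38), which gave the coordinates.

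Before the data were examined, the comparisons, alternatives, gene lists and the rule for named genes were fixed. The design had assumed FPKM values and limma, with edgeR to be used if raw counts were present; since the table holds counts, edgeR's quasi-likelihood test is the main test. Counts were filtered with filterByExpr (11934 genes left), scaled with TMM (factors 0.954 to 1.04) and fitted with 1 term per group over all 8 libraries, which share 1 estimate of the spread with 4 residual degrees of freedom. The biological coefficient of variation was 12.9%. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes are said to have risen or fallen, and the interaction term tests whether the drugs' log2 effects add up. CPM values use TMM library sizes, with no count added for group means and a prior count of 2 for principal components.

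Named genes were taken by a fixed rule. In each comparison with control these are the 10 largest rises and 10 largest falls, and in the others the 5 largest in each direction, among genes past the threshold with a mean of at least 2 FPKM in the higher group and no overlap between the libraries of the groups (a condition not set for the interaction). Gene models without an ordinary symbol were left out, 48 for talazoparib, 77 for the combination and 66 for the combination against romidepsin. Fixed whatever their values were Hdac1, Hdac2, Hdac3, Parp1, Parp2, Cdkn1a, H1f0, Abcb1a, Abcb1b and Mki67. Of each list described, the 2 members with the smallest p in each direction could be named.

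The 31 lists, written from general knowledge, were p53 targets, homologous recombination and Fanconi genes, non-homologous end joining, base excision and single-strand break repair, DNA replication, mitosis, CDK inhibitors, pro-apoptotic and anti-apoptotic genes, interferon-stimulated genes, MHC class I antigen presentation, MHC class II, T-cell identity, T-cell costimulation and inhibitory receptors, ribosome biogenesis and Myc targets, histone deacetylases, histone acetyltransferases and bromodomain genes, genes often induced by HDAC inhibitors, the unfolded protein and integrated stress response, heat shock, ABC drug transporters, neuronal genes, germ-cell genes, NF-kB targets, cholesterol synthesis, NRF2 targets, glycolysis, and markers of B cells, myeloid cells, fibroblasts and erythroid cells. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 168 tests of 28 lists in 6 comparisons. Of these tests 59 passed with the preset correlation and 0 with an estimated one. The test with an estimated correlation was not tried on simulated lists of changed genes. With 4 residual degrees of freedom it may have had little power, so failing it does not show that a list was unchanged. Some genes stand in more than 1 list, such as Cdkn1a, and values of 1 list member are not reported here.

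Overlaps of calls were set against 100 simulated draws of unchanged groups that share the control libraries. On simulated counts with 200 changed genes, the pipeline recovered 20.9%, 70.1% and 84.8% of 1.5-, 2- and 4-fold changes for romidepsin against control (11779 genes, 13 false calls), 23.9%, 68.7% and 87.9% for talazoparib (11778 genes, 14 false calls) and 31.3%, 82.1% and 92.4% for the combination (11791 genes, 6 false calls). For the same comparisons DESeq2 recovered 138, 133 and 148 of 200 genes with 38, 25 and 25 false calls, and limma 118, 116 and 133 with 12, 9 and 5.

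Alternatives were limma with trend on log2(FPKM + 1) and with a pseudocount of 0.1, DESeq2, no filter, a filter of at least 5 FPKM in 2 libraries, quantile normalization, equal-median scaling, only the compared groups in the fit, robust variance estimates, the replicate number as a block, a fold change of at least 2, and each of the 8 libraries left out in turn. A fold change on the log2(FPKM + 1) scale understates the change of low genes. The FPKM values for limma were not scaled with TMM. The TMM factors were 0.954 to 0.980 in libraries without talazoparib and 1.03 to 1.04 in those with it. Lists were also tested with fry. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.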

Results

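Gene expression was measured by RNA sequencing in MBL2 cells, a mouse T-cell lymphoma line from the C57BL/6 strain that arose after infection with Moloney murine leukaemia virus. Cells were left untreated or received a single dose of talazoparib, of romidepsin or of both, and RNA was taken after 24 h. Talazoparib inhibits the PARP enzymes of DNA repair, and romidepsin inhibits histone deacetylases. The doses are not given in the sources used here. Each of the 4 groups (control, romidepsin, talazoparib and combination) held 2 libraries, 8 in all. Total counts were 38913292 and 30727723 reads in the control libraries, 28419156 and 38079995 with romidepsin, 30957491 and 28875070 with talazoparib and 32109346 and 29451131 with both. All 12260 genes listed had at least 1 read in every library, and 11934 were tested. Levels are given as CPM (read counts scaled to a common library size), mean ± SD with n = 2 libraries per group, and changes as log2 fold changes. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

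Talazoparib set the main division between libraries. The first principal component of the log2 CPM values held 50.3% of the variance and placed the talazoparib and combination libraries at 15.1 to 29.6 and the control and romidepsin libraries at -29.5 to -19.2. Across genes, which are not independent replicates, the libraries of a group correlated at r = 0.985 to 0.992. The talazoparib libraries lay furthest apart, with a root mean square log2 difference of 0.439 against 0.327 to 0.376 in the other groups. The ribosomal RNA gene Rn45s, a sign of ribosomal carry-over in polyA libraries, took 0.520% and 0.394% of the reads in the talazoparib libraries and 0.135% to 0.235% in the other 6.

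**Figure D1:**
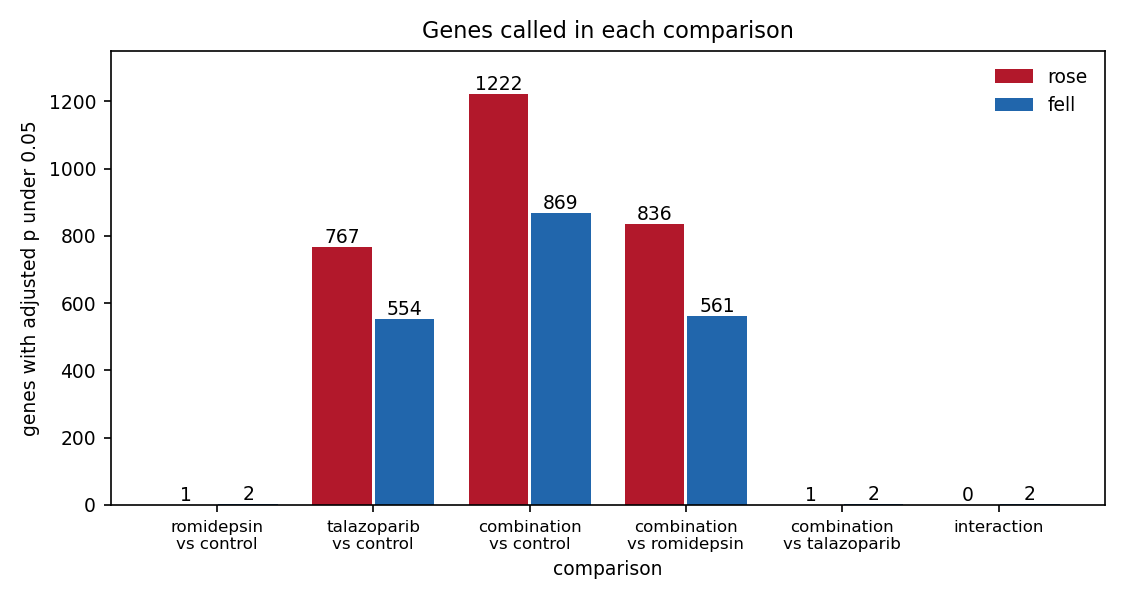
Number of genes (vertical axis) with an adjusted p under 0.05 in each of the 6 comparisons (horizontal axis), with rises in red and falls in blue. The combination against control has the tallest bars (1222 and 869 genes), and the romidepsin, combination against talazoparib and interaction comparisons hold 2 or 3 genes each.

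The comparison of talazoparib with control asked what the PARP inhibitor did alone. After 24 h, 767 genes rose and 554 fell. Cdkn1a (gene ID 12575, chromosome 17, 29090979 to 29100722), which encodes the cyclin-dependent kinase inhibitor p21, rose from 18.5 ± 1.13 to 126 ± 17.3 CPM. Mcam (gene ID 84004, chromosome 9, 44134658 to 44142727), an adhesion molecule of the cell surface, rose from 7.81 ± 0.849 to 69.6 ± 3.84 CPM. Tcf7 (gene ID 21414, chromosome 11, 52246527 to 52283383), a transcription factor of T-cell development, fell from 1739 ± 0.847 to 734 ± 38.6 CPM. Among gene groups, p53 targets, interferon-stimulated genes and T-cell costimulation genes lay higher, and genes of cholesterol synthesis, glycolysis and the stress response lay lower. None of these lists passed with an estimated correlation (adjusted p = 0.162 to 0.596 with an estimated correlation, camera). No list passed that test in any comparison, so it does not tell changed lists from unchanged ones here. Coordinates are on GRCm38 (mm10).

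The other genes with the largest rises were Ces2e (log2 3.43), which encodes a carboxylesterase, Cd80 (3.32), the ligand of Cd28 and Ctla4, Mdm4 (2.69), a regulator of p53, Ak1 (2.52), an adenylate kinase, Ccdc153 (2.52), Mzb1 (2.47), a protein of B and plasma cells, the mitochondrial creatine kinase gene Ckmt1 (2.43) and the desmin gene Des (2.35). With Cdkn1a (2.77) and Mcam (3.15), their adjusted p ran from 9.34e-05 to 0.00253 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cd80 was expressed at 0.687 ± 0.172 CPM in control and 6.97 ± 0.720 CPM with talazoparib, and Mdm4 (gene ID 17248, chromosome 1, 132986105 to 133030587) at 39.8 ± 10.7 and 257 ± 3.94 CPM. On the log2(FPKM + 1) scale, which understates the change of low genes, limma gave the rises of Cd80 and Ak1 as 1.90 and 1.35.

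The largest falls were in Tdg (log2 -2.79), a DNA glycosylase, the histone H2B genes Hist3h2ba (-2.10) and Hist2h2be (-1.22), Gtdc1 (-1.59), Aasdhppt (-1.46), Spp1 (-1.31), which encodes osteopontin, the linker histone gene H1f0 (-1.27), Tcf7 (-1.24), Zpbp (-1.18) and Pou2f2 (-1.16), which encodes the transcription factor Oct-2, with adjusted p of 0.000502 to 0.0431 (edgeR's quasi-likelihood test, Benjamini-Hochberg). H1f0 (gene ID 14958, chromosome 15, 79028212 to 79030504) went from 258 ± 14.7 to 107 ± 27.9 CPM, and Pou2f2 from 162 ± 16.2 to 72.4 ± 18.3 CPM. Tdg stood at 105 CPM in control 1 and 18.6 in control 2. Without control 1 its log2 fold change was -1.05. Its call was lost when any library but control 2 was left out, in limma, with robust variance estimates or with only the compared groups (adjusted p = 0.0598 to 0.159 without those libraries, and 0.00533 to 0.159 over all alternatives), and its log2 fold change was -2.93 to -2.66 without the others of these libraries. The call of Hist3h2ba was lost without control 1 or 2, talazoparib 1 or 2, or combination 1 or 2 (adjusted p = 0.186, 0.0745, 0.0657, 0.0855, 0.0541 and 0.0542, and 0.000379 to 0.186 over all alternatives), while its log2 fold change was -2.43 to -1.66 without them. That of Hist2h2be was lost without any library but talazoparib 1 and with only the compared groups (adjusted p = 0.0551 to 0.205 without those libraries, and 0.00153 to 0.205 over all alternatives), and its log2 fold change was -1.91 without talazoparib 1 and -0.76 without talazoparib 2. Spp1 passed neither without control 1, control 2 or talazoparib 2 (0.0713, 0.117 and 0.0599) nor with only the compared groups (0.0679, and 0.000903 to 0.117 over all alternatives), and its log2 fold change was -0.73 on the log2(FPKM + 1) scale. Zpbp was lost without control 1 or control 2 (adjusted p = 0.0670 and 0.0617, and 2.02e-07 to 0.0670 over all alternatives) and Pou2f2 without control 2 (0.0617, and 5.37e-09 to 0.0617 over all alternatives). Without those libraries the log2 fold changes were -1.50 to -1.11 for Spp1, -1.19 to -1.18 for Zpbp and -1.06 for Pou2f2.

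Of 24 tested p53 target genes, 16 rose and none fell after talazoparib, and 18 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.99 (camera, adjusted p = 1.33e-28, and adjusted p = 0.162 with an estimated correlation). The clearest members were Cdkn1a and the cyclin G1 gene Ccng1, which rose by 1.63 on the log2 scale. Of 28 interferon-stimulated genes, 9 rose, among them the antiviral genes Mx1 (1.25) and Rsad2 (0.93), and 1 fell. Adjusted over the list alone, 15 rose and 1 fell (camera, adjusted p = 4.51e-06, and adjusted p = 0.381 with an estimated correlation). Of 16 T-cell costimulation and inhibitory receptor genes, 6 rose, led by Cd80 and the interleukin-2 receptor gene Il2rb (0.99), and Pdcd1, which encodes PD-1, fell by 0.44 on the log2 scale. Adjusted over the list alone, 8 rose and 1 fell (camera, adjusted p = 0.000142, and adjusted p = 0.186 with an estimated correlation). Among 7 tested ABC drug transporter genes, Abcb1b (gene ID 18669, chromosome 5, 8798147 to 8866314), which encodes a multidrug efflux pump, rose from 97.1 ± 5.55 to 253 ± 14.4 CPM, and Abcc5 rose by 0.90 on the log2 scale. Of the list 3 genes rose when adjusted over the list alone (camera, adjusted p = 0.000578, and adjusted p = 0.326 with an estimated correlation). Abcb1a, the neighbouring pump gene, stood at 0.945 CPM in talazoparib 1 and 6.37 in talazoparib 2 and did not pass (log2 3.61, adjusted p = 0.0668, edgeR's quasi-likelihood test, Benjamini-Hochberg). It passed without talazoparib 1 (log2 4.41, adjusted p = 0.0130, same test) and in DESeq2 (0.0168, and 0.0130 to 0.318 over all alternatives), and its log2 fold change was 1.66 without talazoparib 2 and 0.65 on the log2(FPKM + 1) scale. Of 8 CDK inhibitor genes only Cdkn1a rose, in the count over all genes and adjusted over the list alone. The list's median of -0.04 was opposite in sign to its mean of 0.35 and to its test (camera, adjusted p = 0.0450, and adjusted p = 0.679 with an estimated correlation). On the log2(FPKM + 1) scale the median was 0.03, and under quantile normalization -0.10.

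Markers of other cell types moved with talazoparib, in libraries where Rn45s took 0.520% and 0.394% of the reads, and also with the combination, where it took 0.183% and 0.172%, within the range of the control and romidepsin libraries. Of 6 tested macrophage and myeloid markers, 2 rose, 4 adjusted over the list alone. Lyz2 went from 3.61 and 3.55 CPM in the control libraries to 11.7 and 11.5. Itgam went from 3.53 and 5.02 to 11.8 and 14.1 (camera, adjusted p = 2.60e-05, and adjusted p = 0.186 with an estimated correlation). The single tested B-cell marker, Cd79b, rose by 1.12 on the log2 scale, also when adjusted over the list alone. Of 5 fibroblast and stromal markers Pdgfra (0.91) and Pdgfrb (1.01) rose and Acta2 fell by 0.83, or 2 rises and 1 fall adjusted over the list alone (camera, adjusted p = 0.731). The erythroid genes Epor (0.32) and Klf1 (0.49) and the germ-cell genes Brdt (0.04) and Piwil2 (0.03) did not pass.

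Of 21 cholesterol synthesis genes, 8 fell and none rose, 15 adjusted over the list alone, with a median of -0.48. Insig1, a regulator of sterol synthesis, fell by 1.05 and Lss, lanosterol synthase, by 0.74 on the log2 scale (camera, adjusted p = 1.80e-09, and adjusted p = 0.462 with an estimated correlation). Of 20 glycolysis genes, 5 fell, among them the glucose transporter gene Slc2a3 (fell by 0.75) and the phosphofructokinase gene Pfkp (fell by 1.02), and 1 rose and 10 fell adjusted over the list alone (camera, adjusted p = 3.68e-05, and adjusted p = 0.596 with an estimated correlation). In the unfolded protein and integrated stress response list of 19, 6 fell, with the asparagine synthetase gene Asns (fell by 0.79) and the serine synthesis gene Psat1 (fell by 0.65) the clearest, and Ern1 rose (0.57). In all, 1 rose and 9 fell adjusted over the list alone (camera, adjusted p = 3.84e-05, and adjusted p = 0.491 with an estimated correlation). Myc fell by 0.85 and the nucleolin gene Ncl by 0.63 on the log2 scale among 3 of 26 ribosome biogenesis and Myc target genes that fell, 4 adjusted over the list alone (camera, adjusted p = 0.000143, and adjusted p = 0.720 with an estimated correlation). Of 27 mitosis genes 4 fell, 9 adjusted over the list alone, with Plk1 (fell by 0.46) and Cdc20 (fell by 0.41) leading (camera, adjusted p = 0.00210, and adjusted p = 0.550 with an estimated correlation). Of 20 MHC class I antigen presentation genes 3 fell in both counts, over all genes and adjusted over the list alone, with Psmb10, an immunoproteasome subunit (fell by 0.51), and B2m (fell by 0.37) the clearest (camera, adjusted p = 0.0181, and adjusted p = 0.523 with an estimated correlation). Of 13 heat shock genes only Hsp90ab1 fell (by 0.40), 4 adjusted over the list alone (camera, adjusted p = 0.0341, and adjusted p = 0.608 with an estimated correlation). In the base excision and single-strand break repair list of 24, 4 fell in both counts, over all genes and adjusted over the list alone, among them Ung (fell by 0.79) and Tdp1 (fell by 0.80). The median of -0.04 was 0.05 on the log2(FPKM + 1) scale and -0.09 under quantile normalization (camera, adjusted p = 0.0360, and adjusted p = 0.491 with an estimated correlation).

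The remaining lists showed no camera call. Of 28 T-cell identity genes 5 rose, led by Notch3 (1.57) and Notch1 (1.28), and 3 fell, led by Tcf7 and Gata3 (fell by 0.76), or 5 and 4 adjusted over the list alone (camera, adjusted p = 0.801). Of 23 pro-apoptotic genes 3 rose, led by Bax (1.05) and Fas (1.03), while 4 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.0684), and no member of the anti-apoptotic list of 11 passed in either count (0.939). Homologous recombination and Fanconi genes went both ways, with 3 rises (Fancg 0.46, Rad51d 0.47) and 2 falls (Rad54b -0.59, Bard1 -0.45) among 33, 3 and 3 adjusted over the list alone (camera, adjusted p = 0.724). Among 11 end joining genes only Dclre1c rose (0.40, camera, adjusted p = 0.994), in both counts, and among 36 DNA replication genes none passed in either count (0.358). Cd74 (1.27), the MHC class II invariant chain, was the only one of 6 MHC class II genes to rise, also adjusted over the list alone (camera, adjusted p = 0.0570). Genes often induced by HDAC inhibitors split into 3 rises (led by Cdkn1a and Txnip, 0.82) and 3 falls (led by H1f0 and Mt2, -0.58) among 15, 3 and 4 adjusted over the list alone (camera, adjusted p = 0.643). Kat2b rose (0.42) and Brd7 (-0.39) and Brd8 (-0.44) fell among 16 acetyltransferase and bromodomain genes, 1 and 3 adjusted over the list alone (camera, adjusted p = 0.167), and no histone deacetylase gene of 10 passed in either count (0.688). In the NF-kB list of 14, Nfkbie (0.80) and Csf2 (0.84) rose and Sod2 (-0.44) fell (camera, adjusted p = 0.712), 2 and 1 adjusted over the list alone. In the NRF2 list of 16, Nqo1 (0.62) and Me1 (2.03) rose and Tkt (-0.36) fell, or 2 and 2 adjusted over the list alone (camera, adjusted p = 0.643). Of 9 neuronal genes Nefh fell (by 0.63) in both counts (camera, adjusted p = 0.676).

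The genes of the drug targets did not pass after talazoparib: Parp1 (-0.23), Parp2 (-0.21), Hdac1 (0.09), Hdac2 (-0.29) and Hdac3 (-0.05) had adjusted p of 0.0630 to 0.733 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the values of Hdac1 and Hdac3 changed sign under other settings. Hdac2 passed in DESeq2 (Benjamini-Hochberg adjusted p = 0.0413, and 0.0413 to 0.295 over all alternatives). The proliferation marker Mki67 did not pass either (-0.28, adjusted p = 0.154, edgeR's quasi-likelihood test, Benjamini-Hochberg). Of the 1321 genes called, 285 rose and 29 fell by at least 2-fold, and 58.1% of the calls were rises. Limma on log2(FPKM + 1), without TMM scaling, called 1326 genes, 1017 rises and 309 falls. The count fell to 142 without control 1, 192 without control 2, 824 without talazoparib 2, 814 without combination 1 and 823 without combination 2, and to 342 with only the compared groups in the fit.

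**Figure D2:**
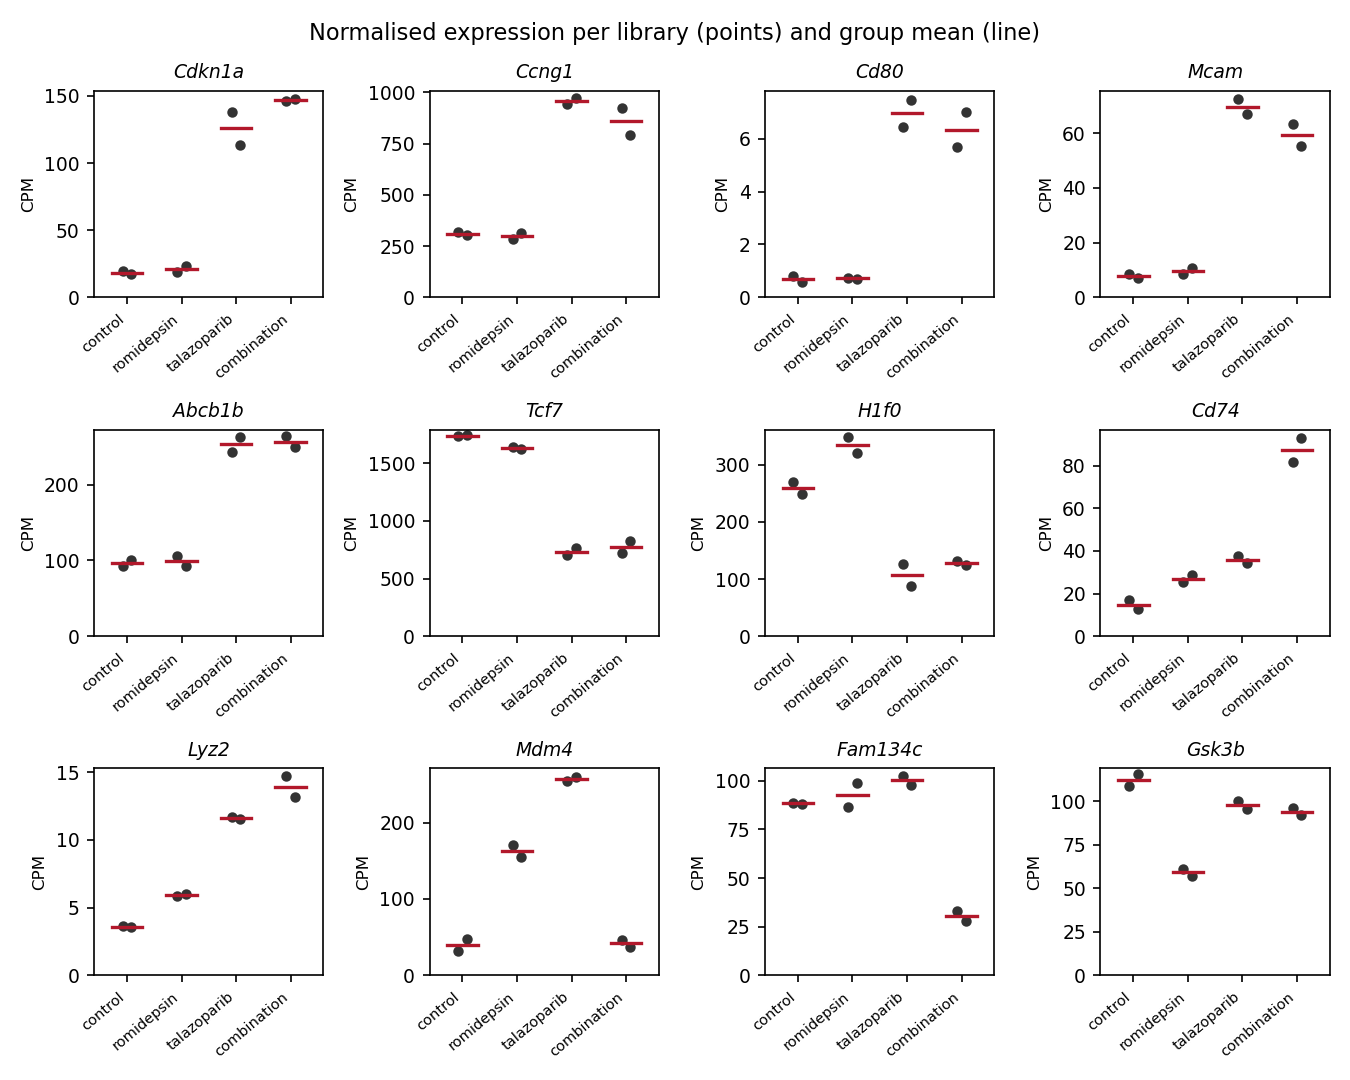
Normalised expression in CPM (vertical axes, from 0) of 12 genes in the 4 groups (horizontal axes), with 1 point per library and a line at the group mean. Cdkn1a lies near 18.5 to 21.0 CPM without talazoparib and 126 to 147 CPM with it, while Mdm4 is high with either drug alone (163 and 257 CPM) and low in control and combination (39.8 and 42.1 CPM).

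Both drugs together were compared with control to show the effect of the combination. In it, 1222 genes rose and 869 fell. Cdkn1a rose to 147 ± 1.18 CPM and Cd74 (gene ID 16149, chromosome 18, 60803849 to 60812652) from 14.9 ± 3.13 to 87.4 ± 7.80 CPM. Fam134c (gene ID 67998, chromosome 11, 101096322 to 101119841), named Retreg3 in the reference annotation, fell from 88.3 ± 0.456 to 30.4 ± 3.83 CPM. The p53, interferon and MHC class II lists lay higher and the glycolysis and stress response lists lower. None of them passed with an estimated correlation (adjusted p = 0.162 to 0.657 with an estimated correlation, camera), and no list did in any comparison. The 10 genes with the largest rises were Cd80 (log2 3.18), Ces2e (3.09), Cdkn1a (2.99), Rab44 (2.98), Mcam (2.92), Ccdc153 (2.64), Ckmt1 (2.57), Cd74 (2.55), Ak1 (2.49) and Des (2.46), with adjusted p of 0.000118 to 0.00144 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Rab44 (gene ID 442827, chromosome 17, 29114128 to 29148980), a small GTPase gene that lies beside Cdkn1a, went from 1.38 ± 0.161 to 10.9 ± 0.241 CPM. On the log2(FPKM + 1) scale limma gave 1.80 for Cd80, 1.5 for Rab44 and 1.33 for Ak1.

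The largest falls were in Tdg (log2 -2.68), Hist3h2ba (-1.88), the stress response gene Trib3 (-1.79), the cytoplasmic actin gene Actg1 (-1.57), Fam134c (-1.54), Gtdc1 (-1.47), Ankrd49 (-1.39), the cohesin subunit gene Stag1 (-1.37), Pou2f2 (-1.34) and the chromatin remodelling gene Dpf2 (-1.29), with adjusted p of 0.000445 to 0.0485 (edgeR's quasi-likelihood test, Benjamini-Hochberg). H1f0 fell by 1.02 and Hdac2 by 0.32 on the log2 scale, and Abcb1b rose by 1.40, while Hdac1 (0.24), Hdac3 (-0.06), Parp1 (-0.20), Parp2 (-0.27), Abcb1a (3.37) and Mki67 (-0.35) did not pass, and Hdac3 changed sign under other scalings. Hdac1 passed under quantile normalization (log2 0.41, adjusted p = 0.0354, and 0.0354 to 0.485 over all alternatives, same test except in limma and DESeq2). Abcb1a and Mki67 passed without talazoparib 1 (adjusted p = 0.0159 and 0.0259) or talazoparib 2 (0.0161 and 0.0259), with only the compared groups (0.0150 and 0.0263) and in DESeq2 (0.0221 and 0.0377, and 0.0150 to 0.361 and 0.0259 to 0.305 over all alternatives). With either talazoparib library left out the log2 fold changes were 3.37 and -0.35. That of Abcb1a was 1.86 without combination 2 and 0.58 on the log2(FPKM + 1) scale. Without control 1 the log2 fold change of Tdg was -0.94. The call of Tdg was lost in limma, with robust variance estimates and without control 1, either romidepsin library or either combination library (adjusted p = 0.0504 to 0.180 without those libraries, and 0.00469 to 0.180 over all alternatives), and its log2 fold change was -3.17 to -2.31 without the last 4 of these libraries. The calls of Hist3h2ba, Trib3, Dpf2 and Hdac2 were lost without any 1 of control 1, control 2, combination 1 and combination 2, with adjusted p of 0.0600 to 0.180, 0.0831 to 0.185, 0.131 to 0.194 and 0.109 to 0.190 without those libraries. Their log2 fold changes there were -2.27 to -1.44, -2.12 to -1.52, -1.36 to -1.24 and -0.36 to -0.28. The adjusted p were 0.00112 to 0.180, 0.00155 to 0.185, 0.000168 to 0.194 and 0.0146 to 0.190 over all alternatives. Dpf2 and Hdac2 were also lost in limma, with stricter filtering and under quantile normalization, Dpf2 and Trib3 with robust variance estimates and Dpf2 with no filter, and limma gave Hdac2 as -0.21. Actg1 was lost without control 2 or combination 1 or 2 (0.0575, 0.0692 and 0.0716, and 3.60e-09 to 0.0716 over all alternatives), and H1f0 without control 1 or combination 2 (0.0554 and 0.0568, and 5.13e-08 to 0.0568 over all alternatives). Without those libraries the log2 fold changes were -1.60 to -1.46 for Actg1 and -0.98 to -0.97 for H1f0.

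Of 24 p53 target genes, 18 rose with the combination, 19 rose and 1 fell adjusted over the list alone, and Ccng1 rose by 1.47 on the log2 scale (camera, adjusted p = 1.85e-22, and adjusted p = 0.162 with an estimated correlation). Interferon-stimulated genes rose in 19 of 28, with Rsad2 (1.18) and Gbp2 (0.76) the clearest, and 1 fell. The counts adjusted over the list alone were 22 and 1 (camera, adjusted p = 1.76e-11, and adjusted p = 0.242 with an estimated correlation). The MHC class II list had a median of 1.01 (0.58 on the log2(FPKM + 1) scale), with Cd74 called over all genes and 4 of 6 adjusted over the list alone (camera, adjusted p = 7.61e-05, and adjusted p = 0.376 with an estimated correlation). Beside it, 4 of 6 myeloid markers rose, 5 adjusted over the list alone, with Lyz2 at 14.7 and 13.1 CPM and Itgam at 21.8 and 22.0 CPM (camera, adjusted p = 9.60e-08, and adjusted p = 0.162 with an estimated correlation), and the B-cell marker Cd79b rose by 1.35. Costimulation and inhibitory receptor genes rose in 7 of 16, or 8 with 1 fall adjusted over the list alone, with Il2rb at 1.14 (camera, adjusted p = 1.20e-05, and adjusted p = 0.186 with an estimated correlation). Abcb1b and Abcc5 (0.84) rose among 7 transporter genes, 3 adjusted over the list alone (camera, adjusted p = 0.00194, and adjusted p = 0.341 with an estimated correlation). Cdkn1a and Cdkn2a (1.54) rose among 8 CDK inhibitor genes in both counts, a list whose median of 0.11 was -0.15 under quantile normalization and 0.20 with a pseudocount of 0.1 (camera, adjusted p = 0.0170, and adjusted p = 0.643 with an estimated correlation).

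With the combination, of 21 cholesterol synthesis genes 8 fell, 11 adjusted over the list alone, Insig1 by 1.01 and Lss by 0.56 on the log2 scale (camera, adjusted p = 6.46e-05, and adjusted p = 0.582 with an estimated correlation). In the glycolysis list 9 of 20 fell and Aldoc rose (1.44), or 1 rose and 10 fell adjusted over the list alone, Slc2a3 by 0.70 and Pfkp by 0.93 (camera, adjusted p = 0.000382, and adjusted p = 0.657 with an estimated correlation). Stress response genes fell in 7 of 19, 8 adjusted over the list alone, with Psat1 (fell by 0.70) and the transcription factor gene Atf4 (fell by 0.85) leading (camera, adjusted p = 6.35e-05, and adjusted p = 0.491 with an estimated correlation). Mitosis genes fell in 6 of 27, 9 adjusted over the list alone, Ccna2 by 0.45 and Cdc20 by 0.48 (camera, adjusted p = 0.000537, and adjusted p = 0.513 with an estimated correlation). Ribosome biogenesis genes fell in 3 of 26 in both counts, over all genes and adjusted over the list alone, Npm1 by 0.46 and Ncl by 0.64 (camera, adjusted p = 0.000521, and adjusted p = 0.735 with an estimated correlation). Base excision repair genes fell in 6 of 24 in both counts, Ung by 0.92 and Tdp1 by 0.78 (camera, adjusted p = 0.0170, and adjusted p = 0.462 with an estimated correlation). The bromodomain genes Brd8 (fell by 0.66) and Brd7 (fell by 0.40) fell among 16 acetyltransferase and bromodomain genes in both counts (camera, adjusted p = 0.0450, and adjusted p = 0.407 with an estimated correlation).

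In the combination 481 genes rose and 32 fell by at least 2-fold, and 58.4% of all 2091 calls were rises. Limma, on FPKM values not scaled with TMM, called 1634 rises and 419 falls. With a pseudocount of 0.1 its median log2 fold change of all genes was 0.102, against 0.00154 in edgeR with TMM. The count was 306 without control 1, 470 without control 2, 617 without combination 1 and 504 without combination 2.

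Most genes called for talazoparib were called for the combination too: 1156 of 1321 (87.5%), 672 rises and 484 falls, with 1 gene in opposite directions. That gene, Rapgef3, is named here after its values were seen: it fell by 0.48 with talazoparib and rose by 0.38 with the combination. The fall was lost in limma, with only the compared groups and without control 1, control 2 or talazoparib 2 (adjusted p = 0.0516 to 0.117 without those libraries, and 0.00231 to 0.117 over all alternatives), and the rise without any 1 of the control and combination libraries (0.0870 to 0.182, and 0.0193 to 0.182 over all alternatives). The log2 fold changes there were -0.52 to -0.45 and 0.34 to 0.40. Independent lists of these sizes would share 78.5 rises and 40.3 falls, and unchanged groups simulated against the same controls shared 0.080 genes on average and 2 at most in 100 draws. Those groups held no changed genes, so the draws cannot say what shared controls give at these counts of calls. With a fold change of at least 2, 261 genes were shared. Across genes the log2 fold changes correlated at r = 0.874 against 0.496 simulated, with a covariance of 0.226 against 0.0359 and a difference of 0.190. The 2 controls were not split between the comparisons, which would leave 1 library in each part, so part of the excess may come from the shared controls. Talazoparib against control and combination against romidepsin share no library, and their log2 fold changes correlated across genes at r = 0.761 (Spearman's rho = 0.771), against -0.0529 to 0.0711 in simulated unchanged groups. In both, 874 genes were called, 66.2% of the talazoparib calls.

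Romidepsin against control asked what the histone deacetylase inhibitor did alone. At 24 h, 3 genes passed, 1 rise and 2 falls. Mdm4 rose from 39.8 ± 10.7 to 163 ± 11.2 CPM (log2 2.04), and Gsk3b (gene ID 56637, chromosome 16, 38089001 to 38246084), a serine/threonine kinase gene, fell from 112 ± 5.12 to 59.3 ± 2.74 CPM (log2 -0.92). Tmem254a, named after its values were seen because its level lies below the minimum of the rule for named genes, fell from 3.81 ± 0.392 to 0.173 ± 0.0139 CPM (log2 -4.44). Its near-identical copy Tmem254c stood at 5.79 and 4.42 CPM in control and 9.58 and 9.35 with romidepsin, so the counting could have divided reads between them. All 3 genes had an adjusted p of 0.0196 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without control 1, romidepsin 1 or 2, or combination 1 or 2, Mdm4 was lost (adjusted p = 0.0726, 0.0877, 0.104, 0.0654 and 0.0645, and 3.61e-25 to 0.104 over all alternatives). Gsk3b was lost in limma and without any 1 of the control, romidepsin and combination libraries (adjusted p = 0.0841 to 0.294 without those libraries, and 3.59e-12 to 0.294 over all alternatives). Tmem254a was lost without the same libraries as Mdm4 (adjusted p = 0.0986, 0.0877, 0.290, 0.0654 and 0.0645, and 2.67e-09 to 0.290 over all alternatives) and was not tested with the stricter filter, and limma gave its log2 fold change as -1.33 on the log2(FPKM + 1) scale. Where these calls were lost with a library left out, the log2 fold changes were 1.77 to 2.09 for Mdm4, -0.98 to -0.88 for Gsk3b and -4.55 to -4.36 for Tmem254a.

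The fixed genes did not pass with romidepsin: Cdkn1a (0.19), H1f0 (0.37), Abcb1a (1.10), Abcb1b (0.04), Mki67 (0.04), Parp1 (-0.01), Parp2 (-0.03), Hdac1 (-0.03), Hdac2 (0.03) and Hdac3 (-0.01) had adjusted p of 0.940 to 0.994 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The values of Abcb1b, Mki67 and the PARP and HDAC genes changed sign under 1 or more other settings. At an unadjusted p under 0.05 there were 522 of 11934 genes, a smaller share than the 0.05 that unchanged genes would give on average. This does not exclude an effect: averaged over both talazoparib arms, the share for romidepsin was larger (876 genes). Limma called 2 genes and DESeq2 8 (5 rises and 3 falls). The count was 1 without control 1, 10 without control 2, 4 without romidepsin 1 (0 of them among the 3 genes above), 1 without romidepsin 2 and 0 without combination 1 or combination 2.

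In edgeR with all libraries no single list member passed over all genes, although DESeq2 called the MHC class II gene Cd74. By camera, 8 lists passed as groups. The median log2 fold changes were 0.51 for 6 MHC class II genes (Cd74 0.86, H2-Ab1 1.84), 0.14 for 28 interferon-stimulated genes (Rsad2 0.50, Gbp2 0.38), 0.23 for 15 genes often induced by HDAC inhibitors (Gadd45a 0.47, H1f0 0.37), 0.11 for 20 glycolysis genes (0.05 under quantile normalization) and 0.08 for 16 costimulation and inhibitory receptor genes (0.05 on the log2(FPKM + 1) scale). Their camera adjusted p were 3.38e-07, 0.000211, 0.000566, 0.0360 and 0.0403, and adjusted p = 0.293, 0.462, 0.491, 0.743 and 0.407 with an estimated correlation. Adjusted over the list alone, 2 MHC class II and 2 interferon-stimulated genes rose and none of the other 3 lists. The 6 myeloid markers moved with them, with a median of 0.58 (0.28 on the log2(FPKM + 1) scale) and 2 rises adjusted over the list alone (Lyz2 0.73, Itgam 0.76; camera, adjusted p = 3.60e-05, and adjusted p = 0.186 with an estimated correlation). Lower as groups were 26 ribosome biogenesis and Myc target genes (median -0.26, Ncl -0.30, Npm1 -0.14) and 36 DNA replication genes (median -0.06, Rrm2 -0.25, Mcm4 -0.15), with camera adjusted p of 8.18e-06 and 0.0302, and adjusted p = 0.678 and 0.574 with an estimated correlation. No member of either passed adjusted over the list alone. The p53 list showed no call (median 0.00, camera, adjusted p = 0.643).

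Of the romidepsin calls, Tmem254a was shared with the combination and Mdm4 and Tmem254a with talazoparib. The log2 fold changes of romidepsin and combination correlated across genes at r = 0.410 against 0.494 simulated from the shared controls (covariance 0.0635 against 0.0357, difference 0.0278). Those of romidepsin and talazoparib correlated at r = 0.320 against 0.494 (covariance 0.0447 against 0.0358, difference 0.00894). Independent lists would share 0.102 rises and 0.146 falls in the former pair and 0.0643 and 0.0928 in the latter. Simulated unchanged groups shared 0.130 and 0.0900 genes on average, 2 at most. Romidepsin against control and combination against talazoparib share no library, and their log2 fold changes correlated across genes at r = 0.250 (Spearman's rho = 0.245), against -0.0410 to 0.0507 in simulated unchanged groups. The simulated genes vary independently. Other splits of the same libraries gave up to 0.372 in size, against 0.255 for the labelled split. A romidepsin effect thus cannot be told apart here from structure among the libraries.

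**Figure D3:**
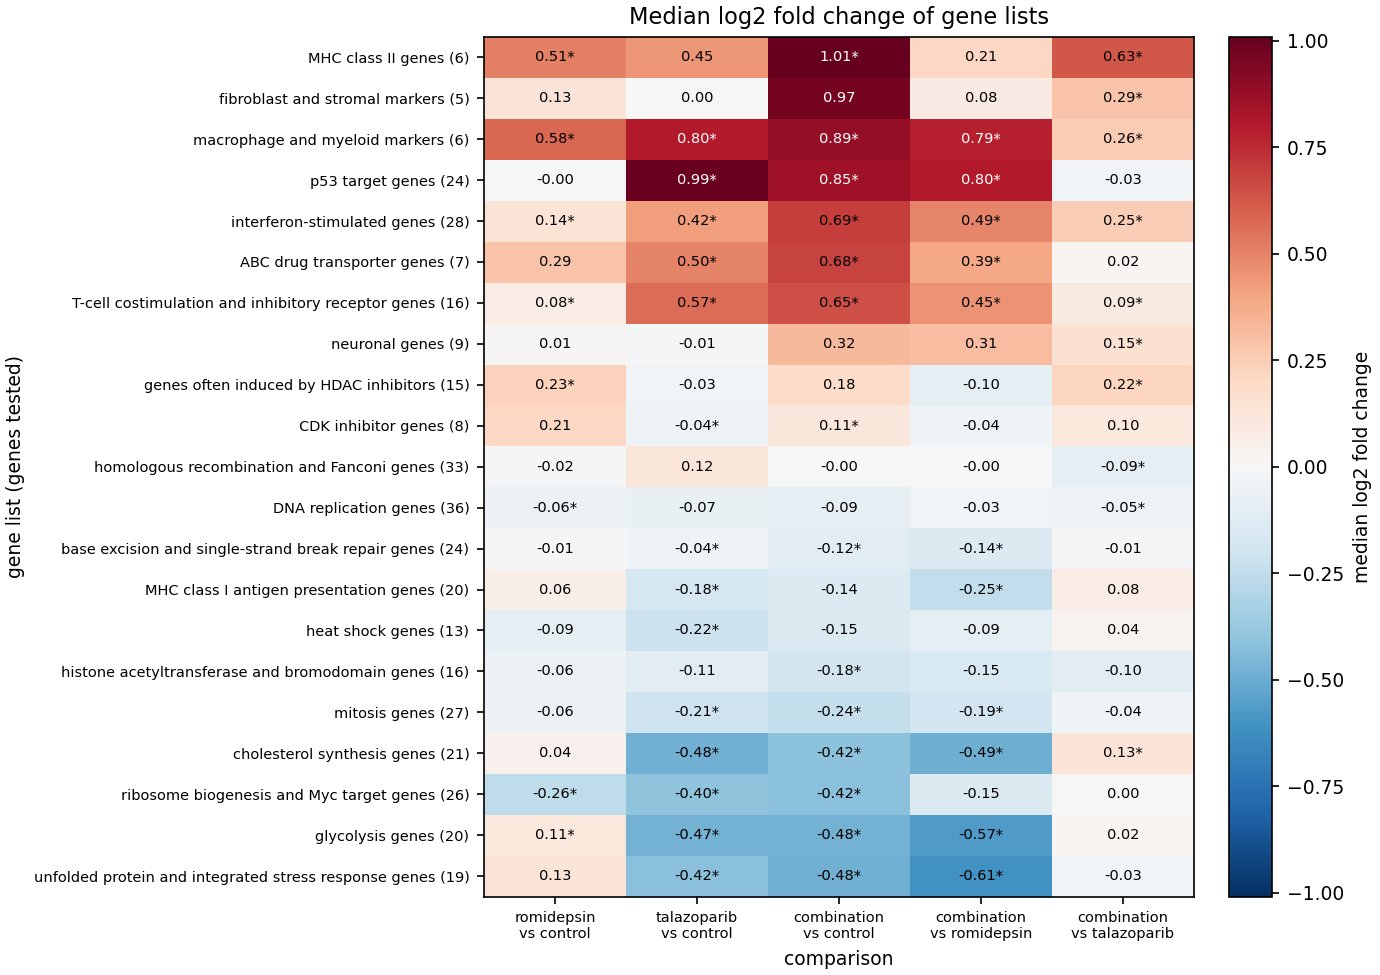
Median log2 fold change (colour and printed value) of 21 gene lists (vertical axis, tested genes in parentheses) in 5 comparisons (horizontal axis), with an asterisk where camera with a preset correlation gave an adjusted p under 0.05. The p53 target list stands at 0.99, 0.85 and 0.80 where talazoparib was added and near 0 where romidepsin was added, and no asterisk holds with an estimated correlation.

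The combination against romidepsin asked what talazoparib added to romidepsin. With both drugs 836 genes rose and 561 fell against romidepsin alone. Cdkn1a stood at 21.0 ± 2.84 CPM with romidepsin and 147 ± 1.18 CPM with both, and H1f0 at 334 ± 19.5 and 127 ± 4.85 CPM. The largest rises were in Ces2e (log2 3.30), Cd80 (3.13), Rab44 (3.09), Cdkn1a (2.80) and Mzb1 (2.69), and the largest falls in Hist3h2ba (-2.29), the stress response genes Trib3 (-2.13) and Ddit3 (-2.01), Mdm4 (-1.95) and Fam134c (-1.61), with adjusted p of 0.000194 to 0.0423 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Abcb1b rose (1.37) and H1f0 (-1.39) and Hdac2 (-0.35) fell, while Hdac1 (0.26), Hdac3 (-0.04), Parp1 (-0.20), Parp2 (-0.24), Abcb1a (2.27) and Mki67 (-0.38) did not pass. On the log2(FPKM + 1) scale the rises of Cd80 and Rab44 were 1.78 and 1.52. The calls of Hist3h2ba and Trib3 were lost without romidepsin 2, combination 1 or combination 2 (adjusted p = 0.126, 0.0833 and 0.158 for the former, 0.141, 0.0935 and 0.175 for the latter, and 5.86e-05 to 0.158 and 0.00595 to 0.175 over all alternatives), with log2 fold changes of -2.67 to -1.53 and -2.47 to -1.59. Robust variance estimates also ended the call of Trib3. The call of Ddit3 was lost in limma, under stricter filtering or quantile normalization, with robust variance estimates and without any 1 of the control, romidepsin and combination libraries (adjusted p = 0.0544 to 0.229 without those libraries, and 0.0121 to 0.229 over all alternatives), with a log2 fold change of -1.27 without romidepsin 2 and -2.49 to -1.76 without the others.

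Of 24 p53 target genes 16 rose, 18 with 1 fall adjusted over the list alone, Ccng1 by 1.51 on the log2 scale (camera, adjusted p = 3.06e-25, and adjusted p = 0.162 with an estimated correlation). In the interferon-stimulated list 15 of 28 genes rose and 1 fell, 21 and 1 adjusted over the list alone, with Mx1 (1.34) and Rsad2 (0.67) leading (camera, adjusted p = 4.68e-08, and adjusted p = 0.322 with an estimated correlation). Costimulation and inhibitory receptor genes rose in 5 of 16, 5 with 1 fall adjusted over the list alone (Il2rb 1.01, camera, adjusted p = 0.000176, and adjusted p = 0.186 with an estimated correlation). The transporter list passed with Abcb1b alone called, 2 adjusted over the list alone (camera, adjusted p = 0.0181, and adjusted p = 0.445 with an estimated correlation). Myeloid markers rose in 3 of 6 in both counts, Lyz2 by 1.23 and Itgam by 1.6 (camera, adjusted p = 9.14e-05, and adjusted p = 0.186 with an estimated correlation), and Cd79b rose by 1.09. Of 20 glycolysis genes 11 fell, 13 adjusted over the list alone, Slc2a3 by 0.79 and Pfkp by 0.95 (camera, adjusted p = 3.85e-07, and adjusted p = 0.513 with an estimated correlation). Stress response genes fell in 10 of 19, 12 adjusted over the list alone, Atf4 by 0.88 and Asns by 0.75 (camera, adjusted p = 2.32e-07, and adjusted p = 0.407 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 21, 11 adjusted over the list alone, Insig1 by 1.07 and Lss by 0.66 (camera, adjusted p = 2.25e-06, and adjusted p = 0.513 with an estimated correlation). Mitosis genes (Cdc20 -0.38, Ncapg -0.33), MHC class I genes (B2m -0.37) and base excision repair genes (Ung -0.73, Tdp1 -0.77) fell in 2 of 27, 1 of 20 and 4 of 24. Adjusted over the list alone, 6, 7 and 4 fell and 1 MHC class I gene rose. The camera adjusted p of these 3 lists were 0.00558, 0.0221 and 0.0403, and adjusted p = 0.591, 0.523 and 0.491 with an estimated correlation.

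By at least 2-fold 311 genes rose and 41 fell against romidepsin, and 59.8% of the 1397 calls were rises. Limma, on FPKM values not scaled with TMM, called 1272 rises and 276 falls. With a pseudocount of 0.1 its median log2 fold change of all genes was 0.104, against -0.00196 in edgeR with TMM. The count was 711 without control 1, 717 without control 2, 268 without romidepsin 1, 182 without romidepsin 2, 279 without combination 1 and 156 without combination 2.

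The combination against talazoparib asked what romidepsin added to talazoparib. Mdm4 fell from 257 ± 3.94 to 42.1 ± 6.57 CPM (fell by 2.61 on the log2 scale) and Fam134c from 100.2 ± 3.28 to 30.4 ± 3.83 CPM (fell by 1.72). Rapgef3 (gene ID 223864, chromosome 15, 97744770 to 97768419), which encodes the cAMP-responsive exchange factor EPAC1, rose from 29.2 ± 0.202 to 53 ± 1.48 CPM (log2 0.86). These 3 genes had adjusted p of 0.00352, 0.00346 and 0.0489 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). None of the 10 fixed genes passed, with Cdkn1a at 0.22, H1f0 at 0.25, Abcb1a at -0.24, Abcb1b at 0.02, Mki67 at -0.07, Parp1 at 0.03, Parp2 at -0.06, Hdac1 at 0.14, Hdac2 at -0.03 and Hdac3 at -0.01. Without combination 2 Mdm4 and Fam134c were lost (adjusted p = 0.0621 and 0.0510, and 3.56e-43 to 0.0621 and 8.24e-32 to 0.0510 over all alternatives), with log2 fold changes of -2.46 and -1.60. Rapgef3 was lost without any 1 of the 8 libraries (adjusted p = 0.0787 to 0.312), in limma, with no expression filter and with only the compared groups (2.79e-08 to 0.317 over all alternatives), at log2 fold changes of 0.83 to 0.89 over the left-out libraries. In all, 510 of 11934 genes had an unadjusted p under 0.05, again a smaller share than unchanged genes would give on average. Limma called 2 genes, DESeq2 27 (19 rises and 8 falls) and the fit with robust variance estimates 5. The count was 9 without talazoparib 2 and 0 without combination 2.

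As groups, 10 lists passed although no member passed over all genes in edgeR's main fit. DESeq2 called the list members Cd74 and Gbp2, and the fit with robust variance estimates called Cd74. Higher were 6 MHC class II genes (median 0.63, 0.32 on the log2(FPKM + 1) scale, Cd74 1.28), 28 interferon-stimulated genes (0.25, Gbp2 0.49), 15 genes often induced by HDAC inhibitors (0.22, Gadd45a 0.33), 21 cholesterol synthesis genes (0.13, Fdft1 0.36) and 9 neuronal genes (0.15, Syt11 1.14). Camera gave them adjusted p of 1.04e-07, 9.20e-09, 0.00176, 0.00157 and 0.00845, and adjusted p = 0.291, 0.293, 0.516, 0.660 and 0.322 with an estimated correlation. Also higher were 16 costimulation and inhibitory receptor genes (0.09, -0.03 under quantile normalization, Ctla4 0.81), 6 myeloid markers (0.26, Itgam 0.76) and 5 fibroblast and stromal markers (0.29, 0.15 on the log2(FPKM + 1) scale, Col1a1 0.76), with camera adjusted p of 0.0450, 0.000356 and 0.0435, and adjusted p = 0.407, 0.227 and 0.491 with an estimated correlation. Lower were 33 homologous recombination and Fanconi genes (-0.09, Rad51ap1 -0.15) and 36 DNA replication genes (-0.05, Clspn -0.15), with camera adjusted p of 0.00312 and 0.0362, and adjusted p = 0.322 and 0.591 with an estimated correlation. Adjusted over the list alone, 1 MHC class II gene, 1 interferon-stimulated gene, 1 neuronal gene and 2 myeloid markers rose, and none in the other 6 lists.

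The 2 x 2 design also allowed a test of whether the effects of the drugs added up on the log2 scale. Of 11934 genes, Mdm4 and Fam134c departed from additivity, with interaction terms of -4.64 (SE 0.263, adjusted p = 0.00105) and -1.79 (SE 0.157, adjusted p = 0.0159, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mdm4 was raised by each drug alone and stood at 0.08 on the log2 scale against control with both (adjusted p = 0.784, edgeR's quasi-likelihood test, Benjamini-Hochberg), and Fam134c was low in the combination group. The fixed genes lay between -1.34 (Abcb1a) and 0.17 (Hdac1) and did not pass. Fam134c was lost without control 1 or 2, romidepsin 2 or combination 2 (adjusted p = 0.144, 0.0907, 0.0825 and 0.0993, and 1.55e-16 to 0.144 over all alternatives), with interaction terms of -1.78 to -1.67. There were 154 genes at an unadjusted p under 0.05, a smaller share than unchanged genes would give on average, and limma called 2 and DESeq2 7. The count was 4 without control 2, 4 without romidepsin 1, 8 without talazoparib 2 and 1 without combination 2. The lists of ribosome biogenesis and Myc target genes (median 0.25) and cholesterol synthesis genes (0.14) had positive interaction terms as groups, with camera adjusted p of 0.000142 and 0.0450, and adjusted p = 0.720 and 0.743 with an estimated correlation. No member of either passed, adjusted over the list alone included.

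In the authors' deposited table, 1416 genes had an adjusted p under 0.05 for talazoparib against control (924 rises and 492 falls), 1991 for the combination, 1536 for the combination against romidepsin, 11 for romidepsin and 25 for the combination against talazoparib. Of these genes in the authors' deposited table, 1109, 1706, 1187, 3 and 3, in the same order, were also called here in edgeR's main fit. The last 2 overlaps depend on the tool. DESeq2 called 8 genes for romidepsin and 27 for the combination against talazoparib. Most of them are among the authors' genes, such as Cd74, Nsg2 and Exosc1 for the former and Cd74, Ifng and Irf8 for the latter.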

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

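Apart from the interaction test, the simulated recovery, the exchange of libraries, the count of splits and the correlation of the average drug effects, the tests in this part were chosen after the result was seen. The effect of romidepsin on 2 genes differed with and without talazoparib, by a test of the difference itself: the interaction was -4.64 on the log2 scale for Mdm4 (adjusted p = 0.00105) and -1.79 for Fam134c (adjusted p = 0.0159, edgeR's quasi-likelihood test, Benjamini-Hochberg). In 4 other named genes every library moved one way in one setting and the opposite way in the other, without an interaction past the threshold. The romidepsin effect with against without talazoparib differed by 1.03 for Aasdhppt and -0.52 for Mcam, and the talazoparib effect with against without romidepsin by 0.86 for Gsk3b and 0.85 for Rapgef3 (adjusted p = 0.389 to 0.999, same test).

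Mdm4, Fam134c, Gsk3b and Tmem254a changed in steps between groups while few other genes did so with romidepsin. Against a shift between transcripts as the whole source, the longest of the 6 listed transcripts of Mdm4 exceeds the shortest by 271% (1914 to 7105 bases), too little for even a full shift to give the 6.45-fold count with talazoparib, and the 1 listed gene within 100 kb of Mdm4 and of Gsk3b took up 0% of their change. The transcript length of Mdm4 implied by count and FPKM differed between groups by 0.252%, in a measure that moved by over 5% in 5.50% of 3038 well-covered genes with several listed transcripts and 0.0194% of 5148 with 1, although its response in Mdm4 itself was not tested. For Tmem254a a division of reads between near-identical copies may be the source, since the summed family differed from control by at most 0.387 on the log2 scale while Tmem254a itself stood at -4.46 (romidepsin), -3.29 (talazoparib) and -5.10 (combination), as log2 ratios of mean CPM. A shift between transcripts of Fam134c or Gsk3b cannot be told apart from a change in expression: the implied length differed by at most 0.212%, but the transcripts of Fam134c are 3165 and 3179 bases long, and of Gsk3b only 1 length is known; Tubg1 among 11 genes within 100 kb of Fam134c moved the opposite way by 30.5% of the step, between the bounds set for and against reads shared with it, and an effect of the drugs stays open for all 4 genes.

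Only 3 genes passed for romidepsin alone, among genes with at least 1 read in all 8 libraries. Genes silent in any library were not analysed, so genes switched fully on or off by a drug could not be counted. An exchange of a control and a romidepsin library alone is argued against. The other splits of these 4 libraries correlated with the labelled combination against talazoparib at no more than 0.0321 in size. The labelled split gave 0.255. The highest value of all (0.372) came from another pairing of splits. It set control 2, romidepsin 1, talazoparib 2 and combination 2 against the rest. In each group the library named here lay higher on the second principal component (16.0% of the variance). An exchange in both pairs of groups at once, or a difference between libraries shared across groups, could give that value. Both stay open. Small real changes that 2 libraries per group leave uncalled are a candidate explanation: the effects of romidepsin without and with talazoparib correlated across genes at r = 0.250, above every simulated draw (highest 0.0507) but under that pairing, so this cannot be told apart from structure among the libraries. Simulated 2-fold changes were called at 70.1% and 1.5-fold changes at 20.9% in this comparison. The simulation changed many genes at once, larger changes among them. The adjusted threshold is stricter when few genes change, and that case was not simulated. These shares thus cannot say how many 2-fold changes stayed uncalled with romidepsin. The 18 splits that keep both talazoparib arms balanced are too few for a share under 0.05: for the average romidepsin effect the real split called 3 genes and the highest other 4, and 5 splits, the real one included, called at least as many as the real one.

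More genes passed for the combination (2091) than for talazoparib (1321), a difference in counts. Changes of talazoparib alone that lie under the threshold may account for part of it. Of 521 genes called in the combination against romidepsin and not in talazoparib against control, 97.5% had the same sign in both. These comparisons share no library, but their log2 fold changes correlated at r = 0.761 across all genes, so a high share could be foreseen. It shows talazoparib changes of like direction in both settings. How much of the difference in counts comes from them it cannot say. Small romidepsin changes in the direction of the talazoparib changes stay undecided, since the average effects of the drugs correlated across genes at r = 0.149 (Spearman's rho = 0.131), above every simulated draw (highest 0.0544), and in the same test over the 18 splits the real one gave 0.143 against 0.239 in the highest other. The wider spread of the talazoparib libraries also stays undecided: with 1 talazoparib and 1 combination library left out together, the count for the combination was 0.870 to 2.85 times that for talazoparib, lowest without talazoparib 1 and combination 2 (1068 against 1228 genes) and highest without talazoparib 2 and combination 1 (1356 against 476).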

How the results depend on the processing

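The values of single genes under limma on log2(FPKM + 1) and under DESeq2 were added after the data were seen; the other alternatives were fixed earlier. Of 1638 values of 87 gene results (64 of them called), 1454 kept their direction and side of the threshold, 152 lost the call in the same direction, 12 gained it and 20 changed sign, the last all in genes that were not called. With 1 library left out, the lone library of its group is assumed to vary like the others. Counts of called genes over the left-out libraries ran from 0 to 10 for romidepsin, 142 to 1529 for talazoparib, 306 to 2698 for the combination, 156 to 1998 for the combination against romidepsin, 0 to 9 for the combination against talazoparib and 1 to 8 for the interaction. With a fold change of at least 2, which leaves out smaller changes by construction, 314, 513 and 352 genes were called for talazoparib, the combination and the combination against romidepsin, and 261 were shared by talazoparib and the combination. With only the compared groups, 342 were called for talazoparib, 3062 for the combination and 1560 for the combination against romidepsin, against 1321, 2091 and 1397 with all groups. DESeq2 called 8 for romidepsin, 27 for the combination against talazoparib and 7 for the interaction, and robust variance estimates 5 for the combination against talazoparib. The cause was not tested. With an estimated correlation, 0 lists passed in each of the 6 comparisons. Fry called 2 lists for romidepsin, 6 for talazoparib, 10 for the combination, 5 for the combination against romidepsin, 2 for the combination against talazoparib and 0 for the interaction, where camera called 8, 14, 14, 11, 10 and 2. Of the 59 called list medians, 30 moved by over 1.5 times or changed sign under at least 1 of limma, a pseudocount of 0.1, quantile normalization and equal-median scaling, and 4 changed sign.

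Signs changed as follows, in log2 fold changes near 0. In romidepsin against control Hdac3 was 0.00192 and Parp1 0.010 with equal-median scaling, Parp1 0.00366 with the stricter filter and Mki67 -0.0226 with quantile normalization. Over the left-out libraries Hdac1 ran from -0.123 to 0.0480, Hdac2 from -0.0118 to 0.0621, Hdac3 from -0.0497 to 0.00222, Parp1 from -0.0378 to 0.00537, Parp2 from -0.0908 to 0.0208, Abcb1b from -0.0747 to 0.123 and Mki67 from -0.0517 to 0.103. In talazoparib against control Hdac1 ran from -0.0125 to 0.190. Hdac3 was 0.0426 with limma and 0.0434 with a pseudocount of 0.1, both on FPKM values not scaled with TMM. In the combination against control Hdac3 was 0.0435 with limma, 0.0443 with a pseudocount of 0.1 and 0.00191 with quantile normalization. The cause was not tested.

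The replicate numbers mark no pairing held by all 4 groups. The deviations of same-numbered libraries from their group means correlated at -0.333 to 0.287 over the pairs of groups. Romidepsin correlated negatively with control (-0.156), talazoparib (-0.333) and the combination (-0.107). The pairs without romidepsin correlated positively (0.0820 to 0.287). A difference between libraries that is shared across groups under other numbers thus stays open, and it was not modelled. With the replicate number as a block the counts of called genes were 0 for romidepsin, 860 for talazoparib and 1 for the interaction, and 1 list was called for the interaction. In simulated data with the depth and number of libraries of this series 23.9% of 1.5-fold changes were called for talazoparib, and the depth was not varied.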

Other observations

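The histone genes and the average romidepsin effect were looked at only after their values were seen. Of 10 tested genes with cluster names (Hist followed by a cluster number), 3 fell with talazoparib, 3 with the combination and 4 in the combination against romidepsin, and none rose, with median log2 fold changes of -0.81, -1.24 and -1.46. In the same order 3, 2 and 2 of the 10 lay higher without a call, among them Hist1h4d (1.68) and Hist1h3c (1.10) with talazoparib. Control means ran from 0.101 (Hist1h4d) to 9.55 CPM (Hist2h2be), and most lay under 1 CPM, near the floor. With talazoparib the calls of Hist3h2ba and Hist2h2be were lost without most single libraries, as given above. The medians were negative under every scaling tried, at -0.32, -0.36 and -0.48 on the log2(FPKM + 1) scale, where 1 gene rose with the combination. With talazoparib the H2B genes Hist3h2ba (-2.10) and Hist2h2be (-1.22) and the H2A gene Hist3h2a (-2.48) fell, and so did the genes outside the clusters H3f3b (-0.90), which encodes histone H3.3, H2afx (-0.96), which encodes H2A.X, and H2afz (-0.43), which encodes H2A.Z, with adjusted p of 0.00595 to 0.0457 (edgeR's quasi-likelihood test, Benjamini-Hochberg). H1f0 fell as well, while H3f3a (0.06), which also encodes H3.3, H2afy (0.02), H2afv (-0.03) and H2afj (0.04) did not pass. In the combination against romidepsin H2afy (0.58) did not pass, and Hist1h4i (-1.49) and H2afv (-0.91) fell too. With romidepsin alone 9 of the 10 cluster genes were higher and none passed (median 0.29, and 0.17 on the log2(FPKM + 1) scale and under quantile normalization). Messages of most cluster genes lack a polyA tail, so polyA libraries hold a part of them.

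Averaged over both talazoparib arms, romidepsin against no romidepsin compared 4 libraries with 4, and 3 genes passed: Cd74 rose by 1.07 on the log2 scale, and Fam134c fell by 0.82 and Tmem254a by 3.11 (adjusted p = 0.0440 for each, edgeR's quasi-likelihood test, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 876 of 11934 genes, here a larger share than unchanged genes would give on average. That share was not computed for other splits of the libraries, so it does not settle whether romidepsin is the source. Of 18 splits that keep both talazoparib arms balanced, 5, the labelled one included, called at least 3 genes. The other splits called 2 at the median and 4 at most, so the number of calls does not stand out. Reads of Tmem254a may have been divided between near-identical copies. Cd74 stood at 14.9 ± 3.13 CPM in control, 26.9 ± 2.23 with romidepsin, 36.0 ± 2.45 with talazoparib and 87.4 ± 7.80 with both (SD, n = 2), higher in both arms without overlap of libraries, and Fam134c was lower in 1 arm only. The MHC class II list had a median of 0.66 (camera, adjusted p = 6.54e-11, and adjusted p = 0.162 with an estimated correlation) and the interferon-stimulated genes of 0.16 (2.91e-09, and adjusted p = 0.219 with an estimated correlation). The myeloid markers moved with them, with a median of 0.40 (camera, adjusted p = 1.04e-06, and adjusted p = 0.155 with an estimated correlation), and the genes often induced by HDAC inhibitors had a median of 0.20 (camera, adjusted p = 4.53e-05, and adjusted p = 0.301 with an estimated correlation). Also higher were the costimulation and inhibitory receptor, cholesterol synthesis and neuronal lists, with camera adjusted p of 0.00963, 0.0238 and 0.0238, and adjusted p = 0.219, 0.631 and 0.245 with an estimated correlation. Lower were DNA replication (median -0.06), ribosome biogenesis and Myc target (-0.13), homologous recombination and Fanconi (-0.06) and mitosis genes (-0.04), with camera adjusted p of 0.00818, 0.00818, 0.0117 and 0.0447, and adjusted p = 0.394, 0.738, 0.245 and 0.624 with an estimated correlation.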
